A study of Mus musculus with 9 samples.

How the data were processed

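RNA sequencing libraries of 3 uninjured cortices, 3 injured cortices and 3 reactive cultures were analysed, 9 in all, grouped as the sample labels give them. The values used are raw gene counts as deposited by the authors, whose processing notes name HISAT2 for alignment to GRCm39, without versions. The counting tool, strand setting and gene annotation are not given in the sources used here. Sequencing reads were not analysed here. The file held 56748 genes, of which 19741 had 0 counts in every library, and total counts per library ranged from 12205049 to 24302770. Of the gene symbols, 77 were shared by more than 1 gene. The gene with the highest total count kept the symbol, and the others, 882 genes, were named by identifier. Of 519 list members, 3 were matched by an older symbol.

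Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough counts by filterByExpr at its defaults were tested, 18093 in all, after scaling by the trimmed mean of M values (TMM). A quasi-likelihood model with a mean for each group (6 residual degrees of freedom) gave each comparison, with Benjamini-Hochberg adjustment over all genes tested and calls at an adjusted p under 0.05. Levels are TMM-normalised CPM for genes, with n = 3 per group, and CPM of the library total for sums over lists and for Xist, Ddx3y and receptor genes. Changes are log2 fold changes ± SE. Principal components used log2 CPM with a prior count of 2 for the 500 most variable genes. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and a ratio with 1 to 3 counts has a 95% counting interval.

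Gene lists were fixed before the data were examined, 36 in all, of which 35 were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists. Each test was repeated with an estimated correlation and with fry. Members were counted by the test over all genes and also adjusted over the list alone. Named genes followed a rule set at the same time: the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 10 CPM and no overlap between groups, a panel of 28 genes, up to 4 members of each list with the smallest adjusted p, and called exceptions to a list. Some results under this rule are not reported here. Outside that rule, Pcna, Cd79a, Cd79b, Ms4a1, Trem2, Sparc, Mmp2, Xist, Ddx3y, Cyba, Fcgr3, Cd53 and, in cultures against injured cortex, Timp1 were chosen after their values were seen.

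Alternatives were DESeq2 size factors, upper-quartile factors, library sizes without the 100 most abundant and the mitochondrial genes, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, 1 CPM in 3 libraries, a fit of the 2 groups compared alone, glmTreat against a log2 fold change of 1, a block for the replicate number, and each library left out in turn. Leaving out uninjured replicates 2 and 3 together was chosen after seeing the data; the remaining uninjured library is then assumed to vary like the other groups. Gene lists were tested again under only part of these alternatives, as stated below. Overlaps of the comparisons, which share libraries, were set beside 20 simulations.

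The analysis was tested on simulated data with the spread and depth of these libraries. Of 4-fold changes, 66.7% were called between injured and uninjured cortex, 79.5% between cultures and injured cortex and 72.7% between cultures and uninjured cortex, and of 2-fold changes 11.0%, 23.6% and 12.5%. False calls were 3.8%, 3.7% and 6.5% of the calls. The simulated groups had the levels of uninjured cortex, with at most 220 genes changed at either fold in any comparison. These rates therefore do not cover scaling where many genes change, as in the cultures, or libraries that stand apart from their group. A simulated list that was moved was called, and of 34 unchanged lists 0 were called.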

Results

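Gene expression was measured by sequencing polyadenylated RNA in 9 libraries from the cortex of wild-type C57BL/6J mice, with 3 biological replicates in each of 3 groups. The uninjured and injured cortex groups held freshly dissociated cells, sorted by flow cytometry to leave out debris, dead cells and neurons. The neurons were gated as positive for CD171 (encoded by L1cam) and negative for ACSA-2 (encoded by Atp1b2). The injury was a grid of stab wounds made with a lancet. Reactive cultures were grown from dissected lesion cores in medium with fetal bovine serum and were collected whole, without a sort. The sample labels give 1 day from injury to dissection and 6 days in culture, whereas the design text of the series gives 3 days for injured cortex, and dissection at 24 h followed by 8 days in culture for the cultures. The times are therefore left open here. Total counts ranged from 12205049 to 18577561 per library in uninjured cortex, from 20389561 to 21135163 in injured cortex and from 16667883 to 24302770 in the cultures. The 100 most abundant genes of each library took 23.6% to 33.0% of its counts in injured cortex, 29.1% to 31.6% in uninjured cortex and 44.5% to 45.9% in the cultures.

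The 3 groups separated from each other. Pearson's r across genes, of log2 counts scaled to library size (CPM), was 0.939 to 0.984 between libraries of one group and 0.738 to 0.934 between groups. The first principal component held 87.4% of the variance among the 500 most variable genes and set the cultures apart from both in vivo groups, and the second held 9.7% and set injured from uninjured cortex. Injured replicate 3 lay nearest to uninjured cortex on the second component. Its astrocyte list summed to 8102 CPM against 3623 and 3687 CPM in injured replicates 1 and 2, and its MHC class II list to 5013 CPM against 12756 and 7535 CPM. Uninjured replicates 2 and 3 held counts at genes that cortex does not use: 2003 olfactory and vomeronasal receptor genes summed to 182 and 151 CPM in them and to 14.4 to 44.1 CPM in the other 7 libraries. Xist was at 28.2 CPM in uninjured replicate 1 and at 0 to 0.473 CPM in the other 8 libraries, while the Y-linked gene Ddx3y was between 35.2 and 86.1 CPM in all 9.

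**Figure D1:**
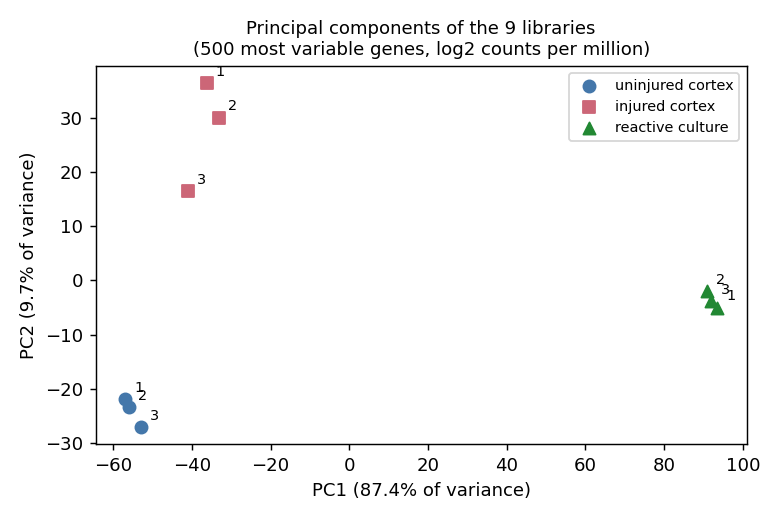
Principal components of the 9 libraries, computed from log2 CPM of the 500 most variable genes. Each point is a library, labelled by its replicate number, the axes are scores on components that hold 87.4% and 9.7% of the variance, and the cultures lie at first-component scores from 90.8 to 93.4, apart from the 6 in vivo libraries at -56.9 to -33.1.

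The comparison of injured with uninjured cortex asks what a stab wound changes in the sorted non-neuronal cells. The cell cycle, neutrophil, pan-reactive astrocyte and A2 reactive astrocyte lists were higher after injury, with a preset and with an estimated inter-gene correlation. Other immune lists were called higher with the preset correlation only. Levels are over all sorted cells of a library, and whether cell makeup or expression within cells changed was not tested. Timp1, an inhibitor of matrix metalloproteinases, had the largest increase among abundant genes, from 0.124 ± 0.0852 to 57.3 ± 31.6 CPM (mean ± SD, n = 3), a log2 fold change of 8.78 ± 0.54 (SE). Gfap, the intermediate filament of reactive astrocytes, rose from 13.9 ± 5.61 to 301 ± 22.9 CPM, and the proliferation marker Mki67 from 0.597 ± 0.0402 to 17.2 ± 1.96 CPM. In edgeR's quasi-likelihood test, 2145 of 18093 genes passed a Benjamini-Hochberg adjusted p of 0.05, 1626 higher and 519 lower, and 1395 and 371 of them had an absolute log2 fold change of 1 or more. At an unadjusted p under 0.05, 4736 genes passed. Of all genes tested, 28.6% had groups that did not overlap, where chance gives 10%. Higher genes made up 75.8% of the calls and 64.0% with upper-quartile factors, which moved the median gene by -0.13. The count depended on single libraries: it was 974 without injured replicate 1, 4102 without injured replicate 3, 1123 without uninjured replicate 2 and 1284 without uninjured replicate 3. It was 462 with both of the latter left out, an alternative chosen after seeing the data that leaves 1 uninjured library. Lower calls numbered 119, 1678, 155, 257 and 42 in these 5 settings, against 519, and higher calls 855, 2424, 968, 1027 and 420, against 1626.

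The other 7 abundant genes with the largest increases were Ifi205 (log2 fold change 7.99), an interferon-inducible gene, Tgm1 (7.08), which encodes a transglutaminase, Slfn4 (6.99), Il1r2 (6.48), the decoy receptor of interleukin-1, Ccnb2 (6.40), a mitotic cyclin, Thbs1 (6.30), which encodes thrombospondin 1, and Il1rn (6.26), the interleukin-1 receptor antagonist. Their adjusted p ranged from 3.92e-06 for Ccnb2 to 7.87e-04 for Ifi205 in edgeR's test, and Il1rn lost its call with uninjured replicates 2 and 3 left out (5.21, adjusted p = 0.0503). Gm10800 had the lowest log2 fold change (-13.7), but its level was 4.58, 2470 and 14716 CPM in the 3 uninjured libraries, and it lost its call with replicates 2 and 3 left out (-3.45, adjusted p = 0.177) and with limma-voom (-10.75, adjusted p = 0.14). It was followed by Upk1b (-2.52), Prelp (-2.12), the gene ENSMUSG00000121079 (-1.95), Id4 (-1.94), C030029H02Rik (-1.93), Scd3 (-1.93) and Etnppl (-1.88). Upk1b fell from 99.9 ± 7.03 to 17.4 ± 6.36 CPM. The log2 fold changes of ENSMUSG00000121079, C030029H02Rik and Scd3 were -1.91, -1.49 and -2.04 with the same libraries left out, where they were not called (adjusted p = 0.0853, 0.169 and 0.101).

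Among the 35 gene lists tested, 23 were called in this comparison by camera with a preset correlation, 18 higher and 5 lower, and 4 of them with an estimated correlation. Those 4 were all higher. The cell cycle list rose in 28 of its 29 genes, and also in 28 when adjusted over the list alone, with a median log2 fold change of 3.45 and examples in Cdk1 (4.81), Rrm2 (4.62) and Mki67 (4.83). Pcna did not pass (0.65, adjusted p = 0.21), except without injured replicate 3 (adjusted p = 0.0165). The list's adjusted p was 6.20e-88, and 0.033 with an estimated correlation. The pan-reactive astrocyte list rose in 7 of 13 genes (9 adjusted over the list alone), among them Serpina3n (6.01), Cd44 (4.25) and Gfap (4.44). The A2 reactive astrocyte list rose in 6 of 11 genes (8 adjusted over the list alone), and the A1 reactive astrocyte list, with Srgn and Gbp2 (both 2.68), in 5 of 11 (also 5 adjusted over the list alone). The A1 call was lost with an estimated correlation (adjusted p = 0.30 with an estimated correlation), and with uninjured replicates 2 and 3 left out (adjusted p = 0.104), as were the calls of Srgn (2.30, adjusted p = 0.119) and Gbp2 (1.87, adjusted p = 0.284). Gbp2 was also lost without uninjured replicate 2 alone (adjusted p = 0.053). The neutrophil list rose in 8 of 13 genes (11 adjusted over the list alone), with Cxcr2 at 5.01 and Mmp9 at 3.62.

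The immune lists that follow, and the cytosolic ribosomal protein list, were called higher with the preset correlation and not with an estimated correlation. Whether recruited cells were added or resident cells changed was not tested. All 10 genes of the monocyte list were higher, 10 adjusted over the list alone, with a median of 4.98 and examples in F10 (7.55), which encodes coagulation factor X, and the chemokine receptor gene Ccr2 (4.74); adjusted p = 0.072 with an estimated correlation. The interferon response list rose in 18 of 19 genes (19 adjusted over the list alone), with Zbp1 at 5.60 and Isg15 at 4.20 (adjusted p = 0.19 with an estimated correlation). Isg15 lost its call with uninjured replicates 2 and 3 left out (3.91, adjusted p = 0.0581). MHC class II genes, which serve antigen presentation, rose in 6 of 7 cases (6 adjusted over the list alone), with H2-Aa at 4.28 and Cd74 at 3.83 (adjusted p = 0.15 with an estimated correlation). The disease-associated microglia list rose in 10 of 19 genes (11 adjusted over the list alone), with Lgals3 at 5.49, Gpnmb at 4.53 and Clec7a at 4.49 (adjusted p = 0.17 with an estimated correlation). The lymphocyte list rose in 11 of 14 genes (12 adjusted over the list alone), with Trac, a T cell receptor constant gene, at 3.06 (adjusted p = 0.19 with an estimated correlation). The B cell genes Cd79b (0.31), Cd79a (1.05) and Ms4a1 (0.88) did not pass, although Cd79a was called with no filter on low counts (adjusted p = 0.0239) and without injured replicate 3 (adjusted p = 0.0431). The inflammatory cytokine list rose in 11 of 18 genes (15 adjusted over the list alone), with Il1b at 4.56 (adjusted p = 0.18 with an estimated correlation), and the cytosolic ribosomal protein list in 18 of 20 (20 adjusted over the list alone) with a median of 1.01 (adjusted p = 0.19 with an estimated correlation). Levels of immune lists varied within injured cortex: the monocyte list summed to 9824, 6071 and 2846 CPM and the interferon list to 6565, 2413 and 1474 CPM in its 3 libraries. The inflammatory cytokine list summed to 16351, 20937 and 10921 CPM there and to 9542, 3035 and 1814 CPM in uninjured replicates 1, 2 and 3.

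Of the 5 lists called lower, 4 stand here and the erythrocyte list below. The mural cell list, of vessel pericytes and smooth muscle, fell in 6 of 14 genes (8 adjusted over the list alone), with a median of -1.23 and examples in Higd1b (-1.78) and Kcnj8 (-1.52); adjusted p = 0.25 with an estimated correlation. Both genes lost their calls with uninjured replicates 2 and 3 left out (-1.17 and -1.11, adjusted p = 0.158 and 0.0903). The oligodendrocyte list fell in 4 of 18 genes (7 adjusted over the list alone), with Aspa at -1.20 and Opalin at -1.14 (adjusted p = 0.19 with an estimated correlation). The calls of these 2 genes were lost with uninjured replicates 2 and 3 left out (-1.31 and -0.88, adjusted p = 0.152 and 0.37), and without uninjured replicate 2 (adjusted p = 0.0793 and 0.0985) or injured replicate 1 (adjusted p = 0.0974 and 0.116). The call of Aspa was also lost without uninjured replicate 1 (adjusted p = 0.05), and the call of Opalin without uninjured replicate 3 (adjusted p = 0.0624) or injured replicate 2 (adjusted p = 0.051). In the astrocyte list, Cldn10 (-1.70) and 2 further genes fell, Gfap rose and the other 16 of 20 did not pass, among them Aqp4 at -0.07 ± 0.24 and Aldh1l1 at 0.08 ± 0.27. Adjusted over the list alone, 6 fell and 1 rose. Its call ended with an estimated correlation (adjusted p = 0.61 with an estimated correlation) and without uninjured replicate 1 (adjusted p = 0.18), injured replicate 1 (adjusted p = 0.101) or injured replicate 2 (adjusted p = 0.106). None of the 14 homeostatic microglia genes was called by edgeR, over all genes or adjusted over the list alone, although camera called the list lower (median -0.52; adjusted p = 0.62 with an estimated correlation). That call ended without uninjured replicate 1, uninjured replicate 2, injured replicate 1 or injured replicate 3 (adjusted p = 0.134, 0.0775, 0.0734 and 0.356). P2ry12, a purinergic receptor of resting microglia, was at 2779 ± 835 CPM in uninjured and 1381 ± 980 CPM in injured cortex (log2 fold change -1.01 ± 0.49, adjusted p = 0.22), and was called lower with no filter on low counts (-0.98, adjusted p = 0.0363) and without injured replicate 2 (-1.74, adjusted p = 0.0298).

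The other 7 lists called in this comparison were 6 called higher and the erythrocyte list, called lower. The extracellular matrix list had 6 of 20 genes higher and 1 lower (6 and 1 adjusted over the list alone), with Timp1 at 8.78 and Thbs1 at 6.30, against Bgn at -1.01 (median 0.45; adjusted p = 0.28 with an estimated correlation). The p53 target list had 2 of 11 genes higher and 0 lower (6 and 0 adjusted over the list alone), with Cdkn1a at 3.01 and Sesn2 at 1.46 (median 0.53; adjusted p = 0.18 with an estimated correlation). The complement list had 3 of 12 genes higher and 0 lower (3 and 0 adjusted over the list alone), with C4b at 3.76 and C3 at 3.76 (median 0.51; adjusted p = 0.19 with an estimated correlation). The glycolysis and hypoxia list had 4 of 19 genes higher and 1 lower (6 and 1 adjusted over the list alone), with Egln3 at 1.50 and Car9 at 2.47, against Ndrg1 at -0.82 (median 0.52; adjusted p = 0.49 with an estimated correlation). The immediate early list had 2 of 18 genes higher and 0 lower (2 and 0 adjusted over the list alone), with Nr4a1 at 2.28 and Egr3 at 2.46 (median 0.42; adjusted p = 0.61 with an estimated correlation). It summed to 19778, 13517 and 5999 CPM in the 3 uninjured libraries and to 15480, 18344 and 14147 CPM in the injured ones. The oligodendrocyte precursor list had 2 of 15 genes higher and 0 lower (2 and 0 adjusted over the list alone), with Gpr17 at 3.83 and Vcan at 2.13 (median 2.08; adjusted p = 0.65 with an estimated correlation). The erythrocyte list had 0 of 5 genes higher and 1 lower (0 and 3 adjusted over the list alone), with Hba-a2 at -1.26 (median -0.86; adjusted p = 0.33 with an estimated correlation). Bgn lost its call without uninjured replicate 2, uninjured replicate 3, injured replicate 1, injured replicate 2 or culture replicate 3 (adjusted p from 0.0519 to 0.117). Sesn2 lost its call without uninjured replicate 2, uninjured replicate 3, injured replicate 1, injured replicate 3, culture replicate 1, culture replicate 2 or culture replicate 3 (adjusted p from 0.0535 to 0.163). Ndrg1 lost its call without uninjured replicate 1, uninjured replicate 2, injured replicate 1, injured replicate 2, culture replicate 1, culture replicate 2 or culture replicate 3 (adjusted p from 0.0535 to 0.192). Gpr17 lost its call without uninjured replicate 2 or uninjured replicate 3 (adjusted p from 0.0587 to 0.0906). Vcan lost its call without uninjured replicate 1, uninjured replicate 2, uninjured replicate 3, injured replicate 1, injured replicate 3, culture replicate 1, culture replicate 2 or culture replicate 3 (adjusted p from 0.0504 to 0.147). Hba-a2 lost its call without uninjured replicate 2, uninjured replicate 3, injured replicate 1, injured replicate 2 or culture replicate 1 (adjusted p from 0.0679 to 0.124). Bgn (-0.29, adjusted p = 0.766), Cdkn1a (1.95, adjusted p = 0.117), Sesn2 (0.74, adjusted p = 0.582), C3 (4.43, adjusted p = 0.0663), Egln3 (1.41, adjusted p = 0.132), Car9 (2.38, adjusted p = 0.201), Ndrg1 (-0.65, adjusted p = 0.37), Nr4a1 (1.44, adjusted p = 0.0663), Egr3 (1.74, adjusted p = 0.25), Gpr17 (2.54, adjusted p = 0.293), Vcan (1.71, adjusted p = 0.47) and Hba-a2 (-1.06, adjusted p = 0.345) lost the call with uninjured replicates 2 and 3 left out. With uninjured replicates 2 and 3 left out, the calls of the glycolysis and hypoxia list (median 0.23, adjusted p = 0.393), the p53 target list (median 0.67, adjusted p = 0.0532), the immediate early list (median -0.07, adjusted p = 0.972) and the oligodendrocyte precursor list (median 1.00, adjusted p = 0.398) ended. Single libraries ended the immediate early call (adjusted p = 0.284 without uninjured replicate 3), the precursor call (adjusted p = 0.0855 without uninjured replicate 3, 0.589 without injured replicate 3) and the erythrocyte call (adjusted p = 0.0702 without injured replicate 3). The precursor call also ended with 1 CPM in 3 libraries (adjusted p = 0.0516). With fry in place of camera, the astrocyte, homeostatic microglia, precursor, erythrocyte and immediate early lists were not called (adjusted p = 0.277, 0.294, 0.24, 0.0867 and 0.138). Bgn, Sesn2, Ndrg1, Gpr17 and Vcan lost their calls in a fit of the 2 groups alone (adjusted p = 0.0895, 0.0971, 0.118, 0.0663 and 0.0957). Sesn2 also lost it with DESeq2 size factors (adjusted p = 0.0551) and upper-quartile factors (adjusted p = 0.0621). Vcan lost it with upper-quartile factors (adjusted p = 0.0527) and limma-voom (adjusted p = 0.146), and Bgn with limma-voom (adjusted p = 0.062).

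**Figure D2:**
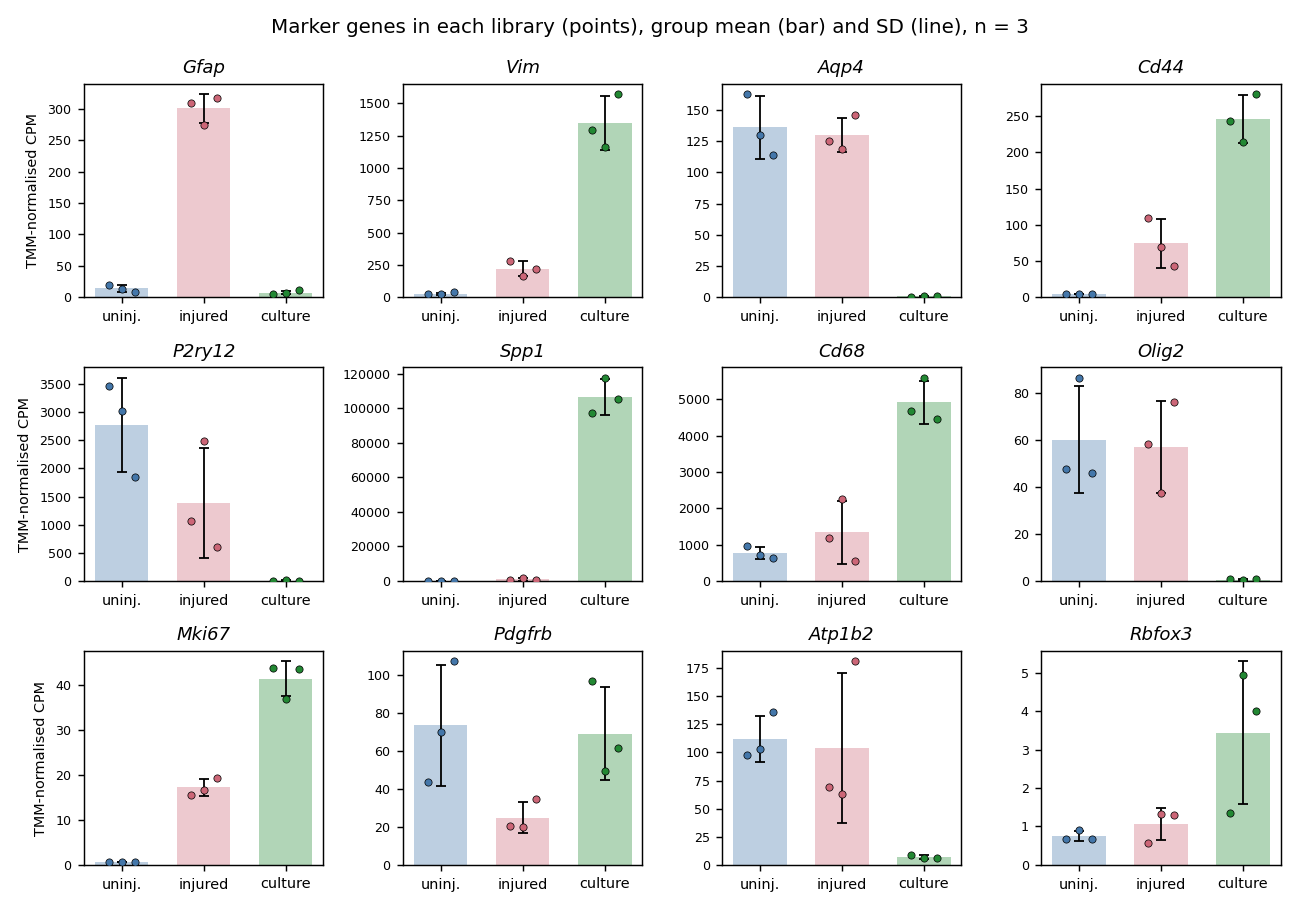
Level of 12 genes of the fixed panel in each library, in TMM-normalised CPM on linear axes that start at 0. Points are libraries, bars are means and lines are SDs over 3 replicates: Gfap was at 301 in injured cortex against 13.9 in uninjured cortex and 7.37 in the cultures, and Spp1 at 106820 in the cultures.

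The comparison of reactive cultures with injured cortex asks how far cells grown from a lesion resemble the cells of the injured tissue. The oligodendrocyte list was lower in the cultures and the YAP and TGF-beta target list higher, with a preset and with an estimated inter-gene correlation. With the preset correlation only, the astrocyte and homeostatic microglia lists were lower, and the disease-associated microglia and extracellular matrix lists higher. Spp1, which encodes osteopontin, rose from 898 ± 752 to 106820 ± 10421 CPM (log2 fold change 6.89 ± 0.76), and Gpnmb, a lysosomal glycoprotein gene of phagocytes, from 43.9 ± 24.7 to 18646 ± 3553 CPM (8.73 ± 0.62). Gfap fell from 301 ± 22.9 to 7.37 ± 2.93 CPM (-5.36 ± 0.37), and the myelin gene Mog from 550 ± 70.4 to 0.498 ± 0.517 CPM (-10.02 ± 0.58). Of 18093 genes, 9057 passed, 3613 higher and 5444 lower, 2331 and 4884 of them with an absolute log2 fold change of 1 or more. The median of all genes was -0.19. Groups did not overlap in 59.7% of the genes. The sort was made in vivo only, so that sorting, culture and time after injury changed together in this comparison. Testing against a log2 fold change of 1 with glmTreat left 4626 calls.

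Among abundant genes, large increases were those of Prl2c2, Crct1, Mmp12, Atp6v0d2, Prl2c3, Mmp13 and Actg2. Mmp12, macrophage elastase, was at 7.52 ± 4.17 CPM in injured cortex and 24634 ± 1870 CPM in the cultures (11.68 ± 0.67), and Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, at 0.508 ± 0.428 and 704 ± 185 CPM (10.48 ± 0.56). The log2 fold change of the collagenase gene Mmp13 was 9.75 and that of Actg2, a smooth muscle actin, 9.60. Crct1 and Prl2c2 had 0 counts in injured cortex and were at least 1230-fold and 2662-fold higher in the cultures, against a floor of 3 counts over the group. Prl2c3 had 2 counts in injured cortex, a ratio of 1327 with a counting interval from 367 to 10961. Prl2c2 and Prl2c3 are near-identical members of one family, so their separate values are uncertain. The largest decreases were those of Neu4, Igkc, Abca8a, Il1b, S100a9, Atp13a5, Ly6d and Mog. Neu4 and Abca8a had 0 counts in the cultures and were at least 453-fold and 330-fold lower. Igkc, Atp13a5 and Ly6d had 1 count each in the cultures, and their ratios of injured cortex to culture were 3912 (interval 702 to 154531), 1665 (299 to 65784) and 1394 (250 to 55065). The cytokine gene Il1b fell from 1440 ± 890 to 0.633 ± 0.359 CPM, and S100a9, a neutrophil gene, from 165 ± 45.6 to 0.0958 ± 0.166 CPM.

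Camera called 25 of the 35 lists in this comparison, 12 higher and 13 lower. With an estimated correlation, 2 of them kept the call, the oligodendrocyte list (adjusted p = 0.019 with an estimated correlation) and the list of YAP and TGF-beta targets (adjusted p = 0.019 with an estimated correlation). The estimates were 0.33 and -0.019, the latter below the preset 0.01. All 18 oligodendrocyte genes fell, over all genes and adjusted over the list alone, with a median of -6.79 and examples in Hapln2 (-8.99) and Mal (-7.41). YAP and TGF-beta targets rose in 9 of 12 cases, also 9 adjusted over the list alone, led by Ccn2 (8.77), Cnn1 (8.69) and Ankrd1 (8.34), while Tgfbi (-2.43) and Skil (-1.57) fell. All 20 astrocyte genes fell, 20 adjusted over the list alone, with a median of -5.13, Cldn10 at -7.68 and Aqp4, a water channel of astrocyte endfeet, at -7.34 (adjusted p = 0.088 with an estimated correlation). Oligodendrocyte precursor genes fell in 14 of 15 cases (14 adjusted over the list alone), with Olig2 at -6.49, and Cspg4 did not pass at 0.83, but was called with no filter on low counts (0.80, adjusted p = 0.0117) and without injured replicate 3 (1.82, adjusted p = 0.00398; the list had adjusted p = 0.35 with an estimated correlation). All 14 homeostatic microglia genes fell, 14 adjusted over the list alone, with Siglech at -9.18, P2ry12 at -7.37 and Tmem119 at -4.97 (adjusted p = 0.17 with an estimated correlation). Disease-associated microglia genes rose in 15 of 19 cases (15 adjusted over the list alone), with Gpnmb, Spp1, Lpl (6.86) and Lgals3 (5.38), while Cst7 fell (-3.67) and Trem2 was at 0.21 ± 0.30 without passing (adjusted p = 0.17 with an estimated correlation for the list).

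The pan-reactive astrocyte list split. Serpina3n (-6.91), Cxcl10 (-8.49), Lcn2 (-6.54), Gfap and 2 other genes fell, whereas Vim (2.61), Timp1 (2.88), Cd44 (1.73) and 3 other genes rose, 6 each way over all genes and adjusted over the list alone, and the list was not called (adjusted p = 0.684). Matrix genes rose in 18 of 20 cases (18 rose and 1 fell adjusted over the list alone), with Lox (8.35) and Bgn (6.27), which encode a collagen crosslinking enzyme and biglycan (adjusted p = 0.088 with an estimated correlation). Their sum, not TMM-scaled, was 4227 ± 272 CPM in injured cortex and 3875 ± 677 CPM in the cultures. Sparc and Mmp2 did not pass (-0.78 and 0.36), although Sparc was called lower with upper-quartile factors, DESeq2, limma-voom and without injured replicate 3 (adjusted p from 0.014 to 0.0406). Fibroblast genes rose in 8 of 14 cases and fell in 2 (9 and 3 adjusted over the list alone), with Col3a1 at 5.87 and Postn at 4.14, against Col15a1 and Pi16 (adjusted p = 0.088 with an estimated correlation). Mural cell genes went both ways: the contractile genes Acta2 (6.41) and Des (4.97) were among 7 that rose, Vtn (-6.22) and Kcnj8 (-4.63) among 5 that fell (8 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.517). Cell cycle genes rose further in 26 of 29 cases (27 adjusted over the list alone), with a median of 1.49 (adjusted p = 0.17 with an estimated correlation). Glycolysis and hypoxia genes rose in 14 of 19 cases, with Egln3 at 3.20 and Ldha at 2.62, and fell in 2, Ndrg1 (-3.12) and Hk2 (-1.13). Adjusted over the list alone, 15 rose and 2 fell (adjusted p = 0.18 with an estimated correlation).

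The neutrophil, MHC class II, interferon response and monocyte lists were called lower in the cultures than in injured cortex. The neutrophil list fell in 12 of 13 genes (12 adjusted over the list alone), and its exception Mmp8, a collagenase, rose (3.77; adjusted p = 0.088 with an estimated correlation for the list). All 7 MHC class II genes fell, 7 adjusted over the list alone, with Cd74 at -6.94 (adjusted p = 0.17 with an estimated correlation). Interferon response genes fell in 17 of 19 cases (17 adjusted over the list alone), with Mx1 at -4.81 (adjusted p = 0.54 with an estimated correlation). Monocyte genes fell in 7 of 10 cases (7 adjusted over the list alone), among them Ccr2 (-6.36) and Ms4a4c (-9.37), while Lyz2 (3.27) and Thbs1 (2.20) rose (adjusted p = 0.56 with an estimated correlation). Their sum was 6247 ± 3492 CPM in injured cortex and 32683 ± 3093 CPM in the cultures. Immediate early genes, which dissociation can also induce, fell in 16 of 18 cases (17 adjusted over the list alone), with Fosb at -7.95 and Nr4a1 at -5.65 (adjusted p = 0.17 with an estimated correlation). Erythrocyte genes, whose counts share reads between near-identical globin copies, fell in 5 of 5 cases (5 adjusted over the list alone), and summed to 1936 ± 736 CPM in injured cortex and 5.11 ± 2.12 CPM in the cultures (adjusted p = 0.081 with an estimated correlation).

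Of the other 9 lists called in this comparison, the lymphocyte, inflammatory cytokine and cholesterol synthesis lists were lower and 6 were higher. The lymphocyte list had 0 of 14 genes higher and 13 lower (0 and 14 adjusted over the list alone), with Cd79a at -7.24 and Cd79b at -4.08 (median -5.27, or -4.94 with genes near 0 counts at their bounds; adjusted p = 0.18 with an estimated correlation). The inflammatory cytokine list had 1 of 18 genes higher and 11 lower (1 and 11 adjusted over the list alone), with Il1b at -11.18 and Ccl12 at -4.26, against Il1rn at 3.08 (median -2.90; adjusted p = 0.47 with an estimated correlation). The cholesterol synthesis list had 0 of 19 genes higher and 13 lower (0 and 13 adjusted over the list alone), with Fdft1 at -1.95 and Hmgcs1 at -1.69 (median -0.94; adjusted p = 0.46 with an estimated correlation).

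The other 6 lists were higher. The p53 target list had 8 of 11 genes higher and 0 lower (8 and 0 adjusted over the list alone), with Mdm2 at 2.20 and Ccng1 at 2.25 (median 1.18; adjusted p = 0.088 with an estimated correlation). The mitochondrially encoded list had 8 of 13 genes higher and 0 lower (8 and 0 adjusted over the list alone), with mt-Nd6 at 1.60 and mt-Co2 at 1.31 (median 0.96; adjusted p = 0.52 with an estimated correlation). The cytosolic ribosomal protein list had 8 of 20 genes higher and 0 lower (4 and 0 adjusted over the list alone), with Rpl5 at 0.96 and Rplp0 at 0.91 (median 0.53; adjusted p = 0.62 with an estimated correlation). The nuclear-encoded respiratory chain list had 6 of 19 genes higher and 0 lower (5 and 0 adjusted over the list alone), with Cox7a2 at 1.06 and Ndufa1 at 1.15 (median 0.50; adjusted p = 0.52 with an estimated correlation). The border-associated macrophage list had 5 of 9 genes higher and 1 lower (5 and 1 adjusted over the list alone), with Pf4 at 3.86 and Folr2 at 3.76, against Cbr2 at -0.93 (median 1.03; adjusted p = 0.18 with an estimated correlation). The A2 reactive astrocyte list had 7 of 11 genes higher and 3 lower (7 and 3 adjusted over the list alone), with Emp1 at 2.52 and Tm4sf1 at 1.60, against Tgm1 at -6.25, B3gnt5 at -1.72, Clcf1 at -0.64 (median 1.64; adjusted p = 0.2 with an estimated correlation). Its sum, not TMM-scaled, was 1649 ± 652 CPM in injured cortex and 1306 ± 69.1 CPM in the cultures. Cbr2 lost its call without injured replicate 2, culture replicate 1 or culture replicate 3 (adjusted p from 0.0568 to 0.109). B3gnt5 lost its call without injured replicate 1 (adjusted p = 0.0522). Clcf1 lost its call without injured replicate 1, culture replicate 1, culture replicate 2 or culture replicate 3 (adjusted p from 0.0556 to 0.0795). Clcf1 also lost it with uninjured replicates 2 and 3 left out (-0.64, adjusted p = 0.0512) and with no filter on low counts (-0.66, adjusted p = 0.119). The A2 call ended without injured replicate 3 (adjusted p = 0.0616).

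**Figure D3:**
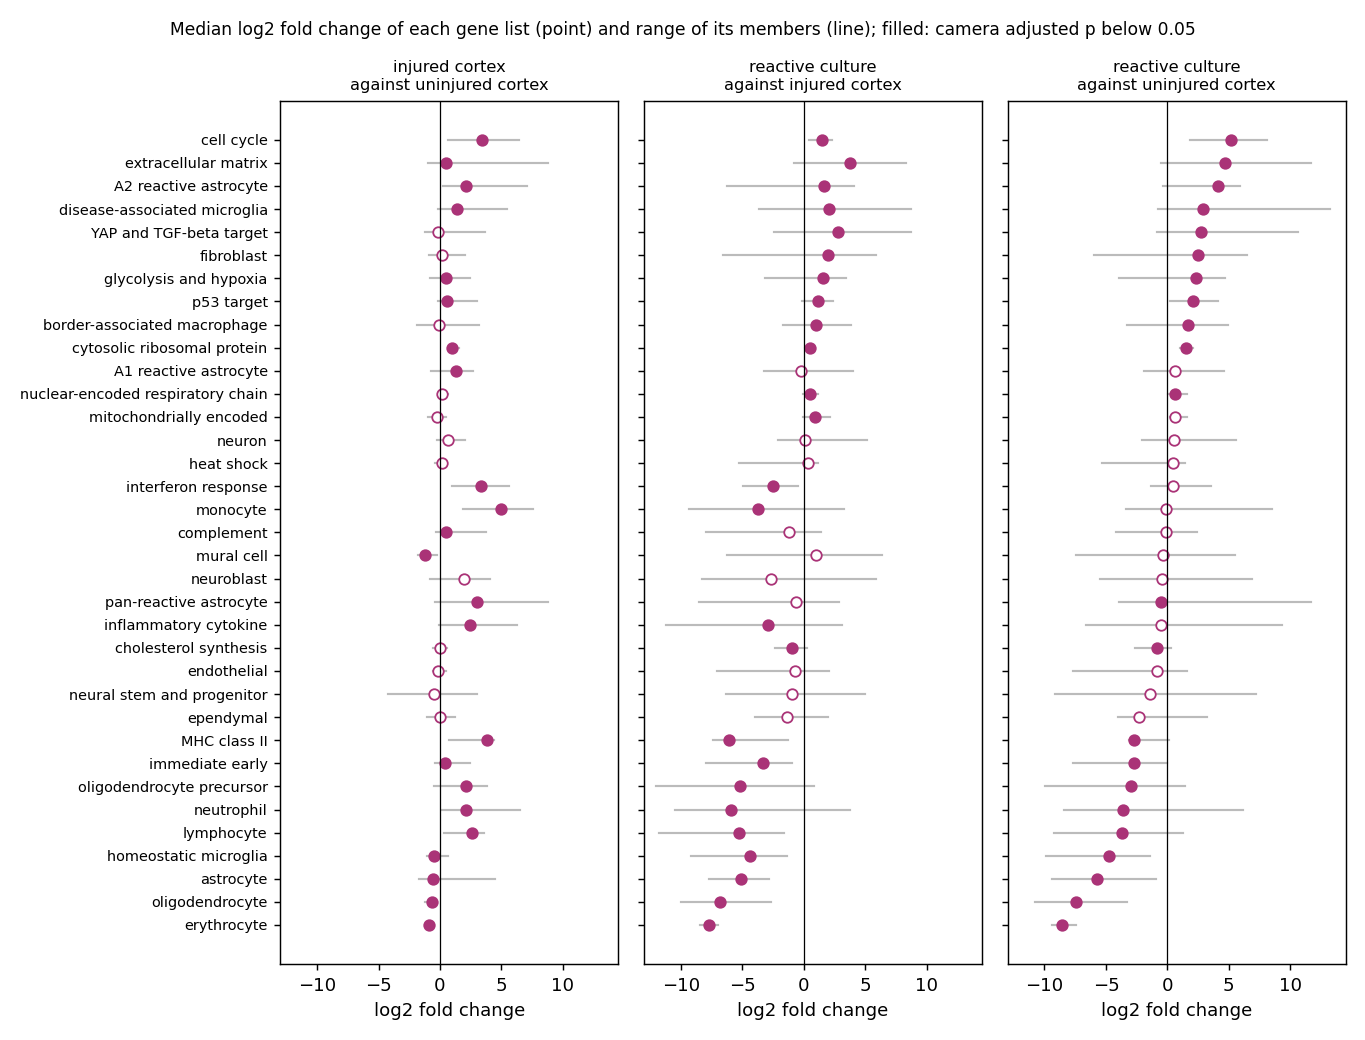
Median log2 fold change of each of 35 gene lists (points) and the range of its tested genes (grey lines) in the 3 comparisons, with filled points for lists called by camera with a preset correlation. Lists are ordered by their median in cultures against uninjured cortex, from -8.55 for erythrocyte genes to 5.20 for cell cycle genes.

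Cultures were also compared with uninjured cortex. The myelin gene Mog fell from 926 ± 243 to 0.498 ± 0.517 CPM (log2 fold change -10.77 ± 0.60), P2ry12 from 2779 ± 835 to 8.31 ± 3.56 CPM (-8.38 ± 0.68), and Spp1 rose from 29.4 ± 3.52 to 106820 ± 10421 CPM (11.83 ± 0.92). Of 18093 genes, 10954 passed edgeR's test, 4969 higher and 5985 lower, with a median of all genes of -0.17, which upper-quartile factors moved by -0.19. The count fell to 6997 with uninjured replicates 2 and 3 left out, and to 6350 against a log2 fold change of 1. The abundant genes with the largest increases were Mmp12 (13.79), Atp6v0d2, Gpnmb (13.26), Crct1, Mmp10, Prl2c2, Mmp13 (12.12) and Spp1. Crct1 and Mmp10 had 0 counts in uninjured cortex and were at least 1001-fold and 662-fold higher in the cultures. Prl2c2 had 1 count in uninjured cortex, a ratio of 6503 (interval 1167 to 256844), and Atp6v0d2 had 3, a ratio of 13034 (interval 4460 to 63203). The largest decreases were those of Abca8a, which had 0 counts in the cultures and was at least 588-fold lower, Gm10800, Atp13a5, Gm42756, Mog, Ptgds (-10.22), the prostaglandin D synthase gene, Olfml1 (-9.97) and Slc6a20a. Atp13a5 and Gm42756 had 1 count and Slc6a20a 2 counts in the cultures, and their ratios of uninjured cortex to culture were 4371 (interval 785 to 172654), 2456 (441 to 97001) and 1139 (315 to 9409). Gm10800 rested on uninjured replicates 2 and 3 here too, and lost its call without them (-1.45, adjusted p = 0.349) and with limma-voom (-9.12, adjusted p = 0.0548).

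Camera called 22 lists in this comparison, 12 higher and 10 lower, and 2 of them with an estimated correlation: oligodendrocyte genes, all 18 lower, with a median of -7.44 (adjusted p = 0.049 with an estimated correlation), and YAP and TGF-beta targets, 9 of 12 higher (adjusted p = 0.049 with an estimated correlation), 18 and 9 of them also adjusted over the list alone. The estimated correlations of these lists were 0.41 and -0.033. All 29 cell cycle genes were higher, 29 adjusted over the list alone, with a median of 5.20 and Mki67 at 6.09 (adjusted p = 0.062 with an estimated correlation). All 20 cytosolic ribosomal protein genes were higher, 20 adjusted over the list alone, with a median of 1.52 (adjusted p = 0.37 with an estimated correlation). All 20 astrocyte genes were lower, 20 adjusted over the list alone (adjusted p = 0.074 with an estimated correlation). Gfap, among them, was 0.92 lower on the log2 scale (-0.92 ± 0.32, adjusted p = 0.0267), and lost its call without uninjured replicate 1 (adjusted p = 0.145), culture replicate 1 (adjusted p = 0.12) or culture replicate 2 (adjusted p = 0.0954). The pan-reactive astrocyte list was called higher although its median was -0.50, since Timp1 (11.66), Cd44 (5.98) and Vim (5.66) were among 6 higher genes and Cxcl10 (-3.92) among 4 lower ones (6 and 6 adjusted over the list alone; adjusted p = 0.37 with an estimated correlation).

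Further lists were called higher in cultures than in uninjured cortex. The extracellular matrix list had 19 of 20 genes higher and 0 lower (19 and 0 adjusted over the list alone), with Timp1 at 11.66 and Bgn at 5.25 (median 4.70; adjusted p = 0.069 with an estimated correlation). Its sum, not TMM-scaled, was 3596 ± 649 CPM in uninjured cortex and 3875 ± 677 CPM in the cultures. The disease-associated microglia list had 17 of 19 genes higher and 0 lower (17 and 0 adjusted over the list alone), with Gpnmb at 13.26 and Lpl at 9.77 (median 2.94; adjusted p = 0.12 with an estimated correlation). The glycolysis and hypoxia list had 16 of 19 genes higher and 2 lower (16 and 2 adjusted over the list alone), with Egln3 at 4.70 and Ldha at 4.13, against Ndrg1 at -3.94, Hk2 at -0.76 (median 2.32; adjusted p = 0.22 with an estimated correlation). The A2 reactive astrocyte list had 8 of 11 genes higher and 0 lower (9 and 0 adjusted over the list alone), with Emp1 at 5.93 and S100a10 at 4.11 (median 4.11; adjusted p = 0.069 with an estimated correlation). The p53 target list had 9 of 11 genes higher and 0 lower (9 and 0 adjusted over the list alone), with Ccng1 at 3.07 and Mdm2 at 2.71 (median 2.08; adjusted p = 0.062 with an estimated correlation). The fibroblast list had 9 of 14 genes higher and 3 lower (9 and 3 adjusted over the list alone), with Mgp at 3.91 and Postn at 3.23, against Col15a1 at -1.79, Slc6a13 at -1.71, Pi16 (median 2.48; adjusted p = 0.12 with an estimated correlation). The nuclear-encoded respiratory chain list had 10 of 19 genes higher and 0 lower (10 and 0 adjusted over the list alone), with Cox5a at 1.46 and Ndufa1 at 1.58 (median 0.62; adjusted p = 0.55 with an estimated correlation). The border-associated macrophage list had 6 of 9 genes higher and 3 lower (6 and 3 adjusted over the list alone), with Pf4 at 3.81 and Ms4a7 at 4.93, against Cbr2 at -1.09, Cd163 at -3.28, Lyve1 at -1.52 (median 1.71; adjusted p = 0.31 with an estimated correlation). Hk2 lost its call without uninjured replicate 2, uninjured replicate 3, culture replicate 1 or culture replicate 2 (adjusted p from 0.0711 to 0.125). Lyve1 lost its call without uninjured replicate 2, culture replicate 1 or culture replicate 2 (adjusted p from 0.0501 to 0.0659). Hk2 (-0.34, adjusted p = 0.518), Slc6a13 (-1.34, adjusted p = 0.11), Pi16 (-4.18, adjusted p = 0.176), Cbr2 (-1.06, adjusted p = 0.0743), Cd163 (-1.90, adjusted p = 0.296) and Lyve1 (-1.42, adjusted p = 0.156) lost the call with uninjured replicates 2 and 3 left out. The call of the border-associated macrophage list ended without uninjured replicate 1 (adjusted p = 0.0502) and with 1 CPM in 3 libraries (adjusted p = 0.0623).

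Further lists were called lower in cultures than in uninjured cortex. The homeostatic microglia list had 0 of 14 genes higher and 14 lower (0 and 14 adjusted over the list alone), with Siglech at -9.62 and Slc2a5 at -9.85 (median -4.79; adjusted p = 0.17 with an estimated correlation). The erythrocyte list had 0 of 5 genes higher and 5 lower (0 and 5 adjusted over the list alone), with Hbb-bs at -8.55 and Hba-a1 at -9.41 (median -8.55; adjusted p = 0.062 with an estimated correlation). The immediate early list had 0 of 18 genes higher and 14 lower (0 and 14 adjusted over the list alone), with Fosb at -7.65 and Klf4 at -3.28 (median -2.75; adjusted p = 0.37 with an estimated correlation). The neutrophil list had 1 of 13 genes higher and 8 lower (1 and 8 adjusted over the list alone), with Ngp at -7.67 and Csf3r at -3.60, against Mmp8 at 6.17 (median -3.60; adjusted p = 0.31 with an estimated correlation). The oligodendrocyte precursor list had 1 of 15 genes higher and 10 lower (1 and 10 adjusted over the list alone), with Olig2 at -6.57 and Olig1 at -7.00, against Cspg4 at 1.43 (median -2.92; adjusted p = 0.55 with an estimated correlation). The lymphocyte list had 1 of 14 genes higher and 8 lower (1 and 8 adjusted over the list alone), with Cd79a at -6.18 and Cd79b at -3.76, against Trac at 1.25 (median -3.67, or -3.33 with genes near 0 counts at their bounds; adjusted p = 0.57 with an estimated correlation). The cholesterol synthesis list had 0 of 19 genes higher and 11 lower (0 and 11 adjusted over the list alone), with Fdft1 at -2.43 and Hmgcs1 at -1.37 (median -0.84; adjusted p = 0.55 with an estimated correlation). The MHC class II list had 0 of 7 genes higher and 6 lower (0 and 6 adjusted over the list alone), with Cd74 at -3.11 and H2-Eb1 at -2.97 (median -2.73; adjusted p = 0.56 with an estimated correlation). Cspg4 lost its call without uninjured replicate 1, uninjured replicate 2, culture replicate 1 or culture replicate 3 (adjusted p from 0.0811 to 0.112). Trac lost its call without uninjured replicate 1 or culture replicate 2 (adjusted p from 0.06 to 0.0607). Cspg4 also lost it with upper-quartile factors (adjusted p = 0.0766) and with 1 CPM in 3 libraries (adjusted p = 0.0527), and Trac with limma-voom (adjusted p = 0.0741). Cspg4 (2.38, adjusted p = 0.0508) and Trac (1.73, adjusted p = 0.0602) lost the call with uninjured replicates 2 and 3 left out. Single libraries ended the call of the cholesterol synthesis list (adjusted p = 0.0951 without uninjured replicate 1, 0.0665 without culture replicate 3) and of the MHC class II list (adjusted p = 0.0544 without uninjured replicate 3, 0.0657 without culture replicate 1), and the MHC class II call also ended with the filter of 1 CPM in 3 libraries (adjusted p = 0.0503). With uninjured replicates 2 and 3 left out, the lymphocyte call (median -1.62, adjusted p = 0.194) and the MHC class II call (median -2.04, adjusted p = 0.0927) ended.

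Injury and culture effects, both taken against uninjured cortex, overlapped. Of the 2145 genes called after injury and the 10954 called in the cultures, 1145 were higher in both, 426 lower in both and 163 of opposite direction. Independent lists of these sizes would share 447 higher and 172 lower genes. Across genes, which are not independent replicates, Pearson's r of the 2 log2 fold changes was 0.493 and Spearman's rho 0.566, against 0.500 and 0.466 in 20 simulations of unchanged groups that share their controls. Pearson's r was thus not above the simulated value. The covariance was 1.45 against 0.136 simulated, a difference of 1.32. With 3 uninjured libraries the controls could not be split into 2 sets of at least 2 libraries, and part of the excess may come from them. The 1571 genes that shared a direction fell to 367 with uninjured replicates 2 and 3 left out and ranged from 738 to 3126 as single libraries were left out. The count was 738 without injured replicate 1, 803 without uninjured replicate 2, 927 without uninjured replicate 3 and 3126 without injured replicate 3.

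Genes that rose after injury took different courses in culture. Of the 1395 that rose by a log2 fold change of 1 or more, 501 were lower in the cultures than in injured cortex, 490 were higher still and 404 were not called. Gfap, Lcn2, Serpina3n, Il1b and Cd74 were among the first, and Timp1, Spp1, Lgals3, Vim and Mki67 among the second. Of the 1395, 35.9% were thus lower and 35.1% higher. Among all 18093 genes tested, 5444 were called lower and 3613 higher in the cultures than in injured cortex. Against uninjured cortex, 945 of the 1395 remained higher in the cultures and 117 were lower. Of the 371 genes that fell by as much after injury, 231 were lower still in the cultures and 49 were higher than in injured cortex. When cultures were simulated with the levels of injured cortex, at most 1 gene that rose after injury was called between culture and injured cortex. That simulation set no difference between the 2 groups, so it gives only the calls that shared libraries would bring. The 501 genes fell to 253 without injured replicate 1 and to 320 without uninjured replicate 2, and with uninjured replicates 2 and 3 left out they fell to 126 and the 490 to 211. The 231 fell to 85 without uninjured replicate 2, 83 without injured replicate 1 and 119 without injured replicate 2, and rose to 622 without injured replicate 3. It was 421 by the DESeq2 Wald test, and 33 with uninjured replicates 2 and 3 left out. The 49 became 103 by the Wald test and 2 with those libraries left out. They became 79, 22 and 17 without uninjured replicates 1, 2 and 3 in turn. They became 11 and 144 without injured replicates 1 and 3, and 30 without culture replicate 1 or 3. Spp1 after injury, at 4.93, was at 5.11 with uninjured replicates 2 and 3 left out and was not called (adjusted p = 0.0632).

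The antigens of the sort were compared through their genes. L1cam was low in every group, at 0.732 ± 0.0891 CPM in uninjured cortex, 1.87 ± 0.690 CPM in injured cortex and 3.76 ± 2.25 CPM in the cultures. It did not differ detectably between the in vivo groups (log2 fold change 1.35 ± 0.51, adjusted p = 0.113 in edgeR's test) or between cultures and injured cortex (1.00 ± 0.48, adjusted p = 0.101). It was higher in the cultures than in uninjured cortex (2.36 ± 0.52, adjusted p = 0.00207), a call that ended with uninjured replicates 2 and 3 left out (adjusted p = 0.0596). Atp1b2, which astrocytes express, was at 112 ± 20.9 CPM in uninjured cortex, 104 ± 66.4 CPM in injured cortex and 6.91 ± 1.62 CPM in the cultures. It was lower in the cultures than in either (-4.02 ± 0.41 and -3.92 ± 0.41), and did not pass between the in vivo groups (-0.10 ± 0.36, adjusted p = 0.894), except without injured replicate 3, where it was called lower (-0.78, adjusted p = 0.0314). The neuronal nuclear gene Rbfox3 was at 0.744 ± 0.134 and 1.06 ± 0.424 CPM in vivo and 3.43 ± 1.86 CPM in the cultures, where it was higher than in injured cortex (1.69 ± 0.54, adjusted p = 0.0207). That call ended without injured replicate 1 (adjusted p = 0.0718), culture replicate 2 (adjusted p = 0.107) or culture replicate 3 (adjusted p = 0.0636). Rbfox3 was also higher in the cultures than in uninjured cortex (2.19 ± 0.56, adjusted p = 0.00501 in edgeR's test). Values of that comparison under the alternatives are not given here.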

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

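Leaving out uninjured replicates 2 and 3 together was chosen after seeing the data, the other alternatives before. For injured against uninjured cortex, 2145 genes were called, and 1369 with only the 2 groups compared, 685 with glmTreat, 462 with uninjured replicates 2 and 3 left out, and 974 to 4102 with single libraries left out (974 without injured replicate 1, 1123 without uninjured replicate 2, 1284 without uninjured replicate 3, 4102 without injured replicate 3). For cultures against injured cortex, 9057 became 4626 with glmTreat and 7152 to 9330 with single libraries left out. For cultures against uninjured cortex, 10954 became 6350 with glmTreat, 6997 with uninjured replicates 2 and 3 left out and 9551 to 12147 with single libraries left out. glmTreat tests against a larger change; otherwise the cause was not tested. Lists called fell from 23, 25 and 22 to 4, 2 and 2 with an estimated correlation, and single libraries gave 20 to 24, 25 to 26 and 21 to 25. A call lost with the estimate did not always go with a high correlation. For the fibroblast list in cultures against uninjured cortex, which lost its call, the estimate was 0.0095 against the preset 0.01. The 1571 genes of shared direction became 367 with uninjured replicates 2 and 3 left out and 738 to 3126 with single libraries left out (803 without uninjured replicate 2, 927 without uninjured replicate 3).

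Genes higher after injury and lower in culture numbered 501, and 126 with uninjured replicates 2 and 3 left out (single libraries 253 to 682; 253 without injured replicate 1, 320 without uninjured replicate 2). Those higher still numbered 490, and 211 (344 to 566). Those lower after injury and lower still numbered 231, and 33, with 421 by the DESeq2 Wald test (83 to 622; 83 without injured replicate 1, 85 without uninjured replicate 2, 119 without injured replicate 2, 622 without injured replicate 3). Those lower after injury and higher in culture numbered 49, and 2, with 103 by the Wald test (11 to 144; 79, 22 and 17 without uninjured replicates 1, 2 and 3 in turn, 11 and 144 without injured replicates 1 and 3, 30 without culture replicate 1 and 30 without culture replicate 3). The cause was not tested.

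L1cam in cultures against uninjured cortex was 2.36, and lost its call with uninjured replicates 2 and 3 left out (2.27; single libraries 1.79 to 2.65); the other 2 comparisons gave 1.00 to 1.56 and 0.43 to 1.33. Atp1b2 in injured against uninjured cortex, -0.10 and not called, ranged from -0.78, called without injured replicate 3, to 0.16 without injured replicate 2, and changed sign without uninjured replicate 3 (0.04), without injured replicate 1 (0.09) and with uninjured replicates 2 and 3 left out (0.08). Its other comparisons ranged from -4.17 to -3.25 and from -4.21 to -3.87. Other changes of sign were of small effects: the immediate early list in injured against uninjured cortex (-0.07 with uninjured replicates 2 and 3 left out, adjusted p = 0.972), Cd79b (-0.06 without injured replicate 2, up to 0.46), Aqp4 (0.10 without uninjured replicate 1), Aldh1l1 (from -0.23 to 0.19 with single libraries left out, 0.00 with DESeq2 size factors, 0.00 with the Wald test, -0.04 with upper-quartile factors, -0.08 without uninjured replicate 2, -0.23 without injured replicate 3, -0.12 with uninjured replicates 2 and 3 left out), and Mmp2 in cultures against injured cortex (-0.05 without culture replicate 1, up to 0.57). The cause was not tested. Among the other values of named genes under the alternatives, 4239 kept direction and side of the threshold, 155 fell short of it and 13 passed it. For reported lists these were 1057, 94 and 0. Lists were not tested again with upper-quartile factors, the Wald test, limma-voom, no filter on low counts, only the 2 groups compared or glmTreat. Over all 35 lists and 3 comparisons, lists that were not called took the other direction in camera in 46 cases and were called in 32. Upper-quartile factors moved the median of all genes by -0.13, -0.07 and -0.19.

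The labels do not say whether the replicate numbers pair the libraries. Deviations from the group means correlated at -0.088 to 0.35 in the 9 between-group pairs of the same number, 3 of them over 0.1. Pairing is therefore unknown. With a replicate block, calls were 2203, 9096 and 11060, lists 23, 25 and 22, shared genes 1639, and the 4 groups above 493, 500, 286 and 47; L1cam was 1.28, 0.93 and 2.20 and Atp1b2 -0.21, -3.76 and -3.97. It called P2ry12 after injury (-1.21, adjusted p = 0.0358) and Cspg4 in cultures against injured cortex (1.14, adjusted p = 0.0491), and ended the calls of Ndrg1 (-0.80, adjusted p = 0.0605) and Vcan (1.87, adjusted p = 0.0643) after injury and of the MHC class II list in cultures against uninjured cortex (-2.71, adjusted p = 0.0611).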

Other observations

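Of the tests below, 3 were chosen after the result was seen: the satellite-like counts of uninjured replicate 1, the share of counts taken by abundant genes, and neurons left in the cultures. The planned test of abundant genes, leaving them out of the library sizes, moved the median of all genes by -0.03 in cultures against uninjured cortex and decided nothing. A test of the size of the receptor counts, run on genes already called, decided nothing either and is not given.

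Counts at 11 satellite-like gene models, among them Gm10800, stood at 3150 and 21023 CPM in uninjured replicates 2 and 3 and at 5.61 CPM or less in the other 7 libraries. A property of all uninjured cortex would need replicate 1 to share them, but its level was 0.00178 of the lower of the 2. This follows from how the pattern was picked and rests on 1 library, so it decides no cause. Reads from genomic DNA may contribute, since the receptor genes, summed, were at least 3.42 times as high in these 2 libraries as in any other. The ratio of satellite-like to receptor counts was 17.3 in replicate 2 and 139 in replicate 3, and with 1 value per library this does not decide whether genomic DNA was the sole source. Another source of the satellite-like counts stays open and was not tested.

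Astrocyte and oligodendrocyte genes were lower in cultures than in uninjured cortex, which a few abundant genes taking the counts did not account for: the 100 most abundant genes took at most 45.9% of the counts of a culture, which leaves the others a log2 share of -0.89, against medians of -5.72 and -7.44 for the 2 lists. Neurons left in the unsorted cultures would raise neuron genes, and against uninjured cortex 7 of 15 rose and 2 fell (median 0.58, list adjusted p = 0.132), with sums of 49.1, 96.7 and 86.1 CPM in culture and 70.7 to 81.9 CPM in uninjured cortex. Neurons as the whole account would need far more, since 0 cultures had a higher sum than every in vivo library, and injured replicates 1 and 3, at 139 and 154 CPM, kept astrocyte sums of 3623 and 8102 CPM against 164 CPM or less in culture. Unlike the fold changes, these sums are not TMM-scaled. The TMM factors were 0.716 to 0.767 in culture, 1.13 to 1.35 in uninjured and 0.938 to 1.39 in injured cortex. Scaling would raise the culture sums relative to the in vivo sums and bring the highest culture sum near the highest in vivo one. The count of 0 cultures is therefore a weak ground. A candidate explanation is a makeup dominated by leukocyte-lineage cells, which the in vivo sort did not exclude: a pan-leukocyte list, which shares no gene with the other lists, had a median of 1.49 against uninjured cortex, with 7 of 12 genes higher and 1 lower (-1.75 to 5.77), but 0.10 against injured cortex, with 4 higher and 2 lower (-3.16 to 1.88); it summed to 6518, 7223 and 7442 CPM in culture, 5665, 5227 and 5430 in uninjured and 9695, 10953 and 5825 in injured cortex, and its 3 most abundant genes in culture, Cyba, Fcgr3 and Cd53, were at 2553, 1728 and 1296 CPM against 540, 1575 and 733 in uninjured cortex. Loss of expression within surviving cells, sorting, culture and time after injury stay open, as none was tested apart.

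Genes called lower in injured cortex could be raised by genomic DNA in uninjured replicates 2 and 3. Of 670 genes called lower without uninjured replicate 1, 67.8% were higher in that library than the injured mean, against 42.6% of other genes. Their median log2 ratio to the injured mean was 0.63 in that library, and their median log2 fold was 2.17 in replicates 2 and 3. The injured libraries that picked these genes also set the mean, which alone can raise their share above that of other genes. The question is therefore left open. With replicates 2 and 3 left out instead, which leaves 1 uninjured library, lower calls went from 519 to 42 and higher calls from 1626 to 420. A biological difference between injured and uninjured cortex stays open.

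Other splits of the 6 libraries of each comparison were counted, and 10 splits cannot give a share under 0.05. For injured against uninjured cortex, 1 of 10 splits gave as many calls, the real one, with 1369 against 0 in the highest other. For cultures against injured cortex, 1 of 10 did, with 7951 against 0, and for cultures against uninjured cortex, 1 of 10, with 10775 against 0.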
